A study of Mus musculus with 2 samples.

How the data were processed

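Uterine polyA RNA of wild-type mice on gestational day 4 was extracted with TRIzol, and libraries were made with a directional kit, per the labels' protocols. Of the 2 samples, 1 was immunoprecipitated with an antibody against m6A and 1 was input. HISAT2 2.2.1, MACS3 3.0.0a7 and the build mm10 are named in the submitters' processing notes. The options used, the input's part in the peak calling and any pooling are not given in the sources used here. The single peak list is deposited with the IP sample and no file of the input sample was used here.

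Each peak has a position, a summit and 4 deposited values. The fold enrichment is a ratio of the pileup plus 1 to the background plus 1, as the deposited values bear out. The p-value and q-value are deposited as −log10. The score equals 10 times −log10 q, with decimals dropped, to within 1 in every deposited peak. The lowest −log10 q was 1.31, which corresponds to a threshold of 0.05. These are the peak caller's own values and were used only to describe, rank and filter peaks within the list. No peaks overlapped, and the smallest gap between neighbours was 117 bp.

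The IP pileup and the background at each summit were solved from the fold enrichment and the Poisson p-value. The pileup came out whole, within 0.05 of the step between whole pileups, for 99.97% of peaks, leaving 7 that did not. What sets the level of the background was not tested. The solver returned the true pileup for 100% of 2000 simulated peaks. These were made with the formula that the solver inverts, so they check the solving and not whether the peak caller used that formula. Exact Poisson intervals of the pileup at a 95% confidence level, with the background taken as known, gave the intervals of fold enrichments. Shares have Wilson intervals, which treat the genes or peaks counted as independent draws. Both cover counting error only, since amplified fragments are not independent molecules and 1 library pair says nothing of the spread between animals.

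Genes were taken from a RefSeq table of 49997 genes on the build GRCm38.p6, the assembly of mm10, which holds gene spans without exons, strand or sequence. The design assigned a peak by its summit in an exon. Spans were used in its place, and a peak counted for a gene only when its summit lay in the span of exactly 1 gene. Regions of the transcript, the DRACH sequence motif, exon lengths and genes with peaks in the 5′ untranslated region, also in the design, were not analysed here for want of exons and sequence. The kit keeps strand but the peaks carry none, so antisense transcripts were not told apart. Coordinates are given counting from 1.

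The 26 gene lists, the alternatives listed at the end of this section and the rule for named genes were fixed before the data were examined. Alternatives chosen after the data were seen are named where the dependence on the processing is described, and some of their values appear in the results. Named genes are the members of the lists, the 20 protein-coding genes with the highest fold enrichment among peaks with −log10 q of at least 5, the 10 with the most peaks and the 10 with the highest −log10 q. Peaks of Hoxa11, Xist and Kcnq1ot1, the genes whose several peaks are mapped and the members named as examples within a list were singled out after their values were seen. Some genes and 1 added list that these rules name are not reported here. The list of mitochondrial genome genes matched only 2 genes, 1 of them with a peak. Further lists for the closing tests and for other gene families were written later, as stated there.

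For each list the number of members with a peak was placed among 10000 random lists of the same size drawn from protein-coding genes and matched on gene span in 20 bins. The design had named exonic length for this. Percentiles place ties midway. The median of the highest fold enrichment per gene was placed among 10000 random lists of genes with a peak matched on background in 20 bins. Lists with under 5 genes with a peak have no enrichment percentile. As a check of the matching alone, 200 lists were simulated from longer genes, with the chance of a peak set to rise with span only. Of these, 5 fell outside the central 95% with matching and 129 without it. The simulation says nothing of exonic length or expression. Positions along gene spans were compared with 1000 random placements in the same spans. Alternatives were −log10 q of at least 5, fold enrichment of at least 4, any overlap or 50% overlap of the peak with the span, unmatched random lists, the median over a gene's peaks and the pseudocount. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.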

Results

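Transcripts carrying N6-methyladenosine (m6A), a methyl mark on internal adenosines of mRNA, were mapped by methylated RNA immunoprecipitation sequencing in the uterus of wild-type mice, taken on day 4 of gestation. In this assay RNA fragments bound by an anti-m6A antibody (IP) are sequenced beside unselected fragments (input). The labels give 1 IP and 1 input sample of polyA RNA, both from day 4. There is no replicate of either, so no p-value across samples can be given, and every difference below describes this 1 peak list. The data are 26584 peaks deposited with the IP sample, positioned on the mm10 build, each with the fold enrichment and significance that the authors' peak caller gave it. The names of all 26584 peaks carry the run name D8NegIP-Posinput, which does not match the day given in the sample labels. The labels' grouping is used here, and whether these peaks belong to the day 4 sample remains unsettled. What NegIP and Posinput stand for is not given. Whether the labelled input served as the background of the fold enrichments and q-values is therefore unsettled too.

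The depth could be recovered from the peaks themselves, because fold enrichment and Poisson significance together fix the number of IP fragments at a summit and the background expected there. The IP pileup at the summit had a median of 18 fragments (quartiles 11 and 31, range 3 to 361), and 5561 peaks (20.9%) rested on fewer than 10. The background had a median of 1.42 fragments on the scale of the IP library. Of backgrounds under 2.5 and above the lowest level, 62.9% were whole multiples of 0.192 within 0.001. The median fold enrichment was 7.14 (quartiles 5.52 and 10.1, range 1.76 to 102.5), and the median peak was 322 bp wide. Intervals given below are 95% intervals that cover counting error only. For a fold enrichment they are exact Poisson intervals of the IP pileup with the background taken as known, and for shares they are Wilson intervals. The Wilson intervals treat the genes or peaks counted as independent draws.

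**Figure D1:**
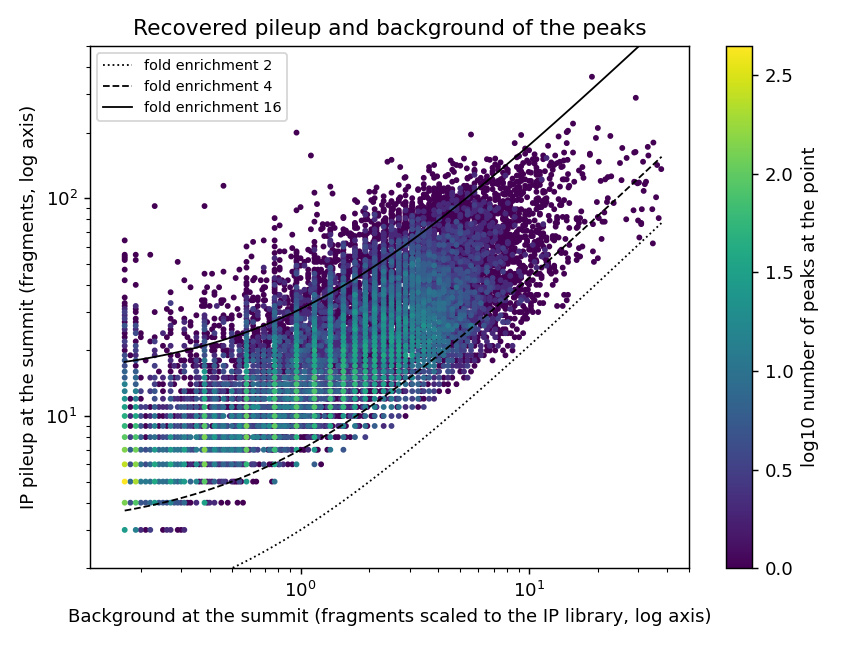
IP pileup against background at the summits of the 26584 peaks, both in fragments on log axes, coloured by the log10 number of peaks at each point (background rounded to 2 decimals), with lines for fold enrichments of 2, 4 and 16. Pileup ran from 3 to 361 fragments, and 1333 peaks lay within 1% of the lowest background level, 0.175.

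The peaks lay mostly in protein-coding genes. Of the 26584 summits, 21038 (79.1%, 78.6 to 79.6) fell in the span of exactly 1 gene and that gene was protein-coding. A further 706 (2.66%) fell in 1 long non-coding RNA gene and 422 (1.59%) in 1 pseudogene. Another 2057 (7.74%) lay in the spans of several genes and were assigned to none of them. In all, 8950 of 21900 protein-coding genes (40.9%, 40.2 to 41.5) had at least 1 peak, against 481 of 12731 long non-coding RNA genes (3.78%, 3.46 to 4.12). Genes with 1 peak made up 43.1% of the protein-coding genes with a peak, genes with 2 to 4 peaks 46.5%, and 105 genes had 10 or more. The share of protein-coding genes with a peak rose with the gene span, from 7.86% of genes under 2 kb to 65.7% of genes over 100 kb. Spans include introns, and the table of genes gave neither exons nor strand, so a summit in a span can lie in an intron or in an antisense transcript.

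Within protein-coding spans, the highest enrichments were in single sites of a varied set of genes. Peaks outside every gene span reached up to 75.6 and are not ranked here. Peak1, which encodes a cytoskeleton-associated pseudokinase, had a fold enrichment of 102.5 (88.8 to 118) at chromosome 9, 56223477 to 56224041, where 200 IP fragments stood over a background of 0.961. Gphn, the gene of the inhibitory synapse scaffold and molybdenum cofactor enzyme gephyrin, followed with 78.7 (65.0 to 94.4) at chromosome 12, 78350788 to 78351123. The others among the 20 highest protein-coding genes ranged from 49.7 in Bptf, a chromatin remodelling subunit, to 36.3 in Tada2b, a subunit of histone acetyltransferase complexes. They included Lats2, a Hippo pathway kinase, at 46.4 (36.9 to 57.5), the cytokine receptor gene Il31ra at 47.0 (35.6 to 60.9), and the imprinted zinc finger gene Plagl1 at 39.1 (31.2 to 48.2). Also among the 20 were Dph5, Znhit6, Tmem178, Dynll1, Trim44, Zbtb10, Ahdc1, Mfap3l, Camk1d, Naa30, Phf23, Basp1 and Fam32a. These are values of the strongest site, and their intervals leave out any counting error of the background. The backgrounds of Il31ra and Tmem178 were 0.192 and that of Camk1d 0.577, and the highest of the 20 was 2.73, in Phf23. Where the background is under 1, the 1 added to it is the larger part of the divisor. The Gphn summit lay 133652 bp, that of Camk1d 85831 bp and that of Peak1 22589 bp from the nearer span end. Others, such as Bptf at 681 bp, lay close to an end. Whether such sites are exons, introns or repeats was not tested. Over all of its 5 peaks, the median of Peak1 was 13.0, and that of Gphn over 7 peaks was 5.83.

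Among protein-coding genes, Dst, which encodes a cytoskeletal linker, had the most peaks, 28, and Col6a3, a chain of collagen VI, had 24. Myh10 (non-muscle myosin), Tnrc18 and Tnxb (tenascin X) had 22 each, Myh11 (smooth muscle myosin) and Sptbn1 (spectrin) 21 each, and Cgnl1 and the histone methyltransferase gene Kmt2d 18 each. These are counts of peaks on the genome and not of m6A sites. The ranking takes no account of gene span, exons or expression. By the q-value of protein-coding genes, Peak1, Zc3h7a and Gphn led. Zc3h7a, a zinc finger gene, had the highest pileup of all, 361 fragments, at a lower fold enrichment of 18.2 (16.4 to 20.2). Trim44, Phf23, the splicing factor genes Son and Snrnp70, Bptf, the uterine transcription factor gene Hand2 and Sec62 completed the 10 protein-coding genes with the highest significance.

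Progesterone signalling genes carried peaks more often than random genes of like span. Of 21 members, 17 (81.0%, 60 to 92.3) had a peak, against a median of 42.9% in 10000 random lists of protein-coding genes matched on gene span, a count at percentile 99.97. Hand2, a stromal transcription factor induced by progesterone, had a fold enrichment of 29.5 (24.9 to 34.8) at chromosome 8, 57320952 to 57322584, with 142 IP fragments. The steroid receptor coactivator gene Ncoa2 stood at 27.7 (22.5 to 33.8), Nr2f2, the gene of the stromal regulator COUP-TFII, at 21.4 (16.5 to 27.4), Gata2 at 17.6 (13.9 to 21.9) and Foxo1 at 16.2 (11.6 to 21.9). The progesterone receptor gene Pgr had 4 peaks. Its strongest, at chromosome 9, 8899837 to 8902081, had 13.8 (10.6 to 17.5), and the others had 7.86, 3.87 and 3.14. Hoxa10, needed for uterine receptivity, had 9.38 (7.90 to 11.1) over a background of 14.0, and Ihh, the epithelial Hedgehog ligand, had 4.26 (1.78 to 9.57) from only 4 fragments. A peak of 17.9 (14.7 to 21.6) in Hoxa11 lay where its span overlaps another gene and was not counted. Areg, Calca and Il13ra2 had no peak. The median of the highest fold enrichment per gene was 13.8, at percentile 99.7 of random lists of genes with a peak matched on background. With the median over each gene's peaks it was at percentile 97.0, inside the central 95%.

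The percentiles of counts compare a list with genes of every kind, expressed in the uterus or not, since expression is not in the data used here. A list of uterine genes can therefore stand above random lists through expression alone. The list percentiles of the enrichment are taken among genes that have a peak, so genes without one do not enter them. They were matched on background but not on the number of peaks per gene, with which a highest value can rise. Whether expression plays a part in them was not tested.

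**Figure D2:**
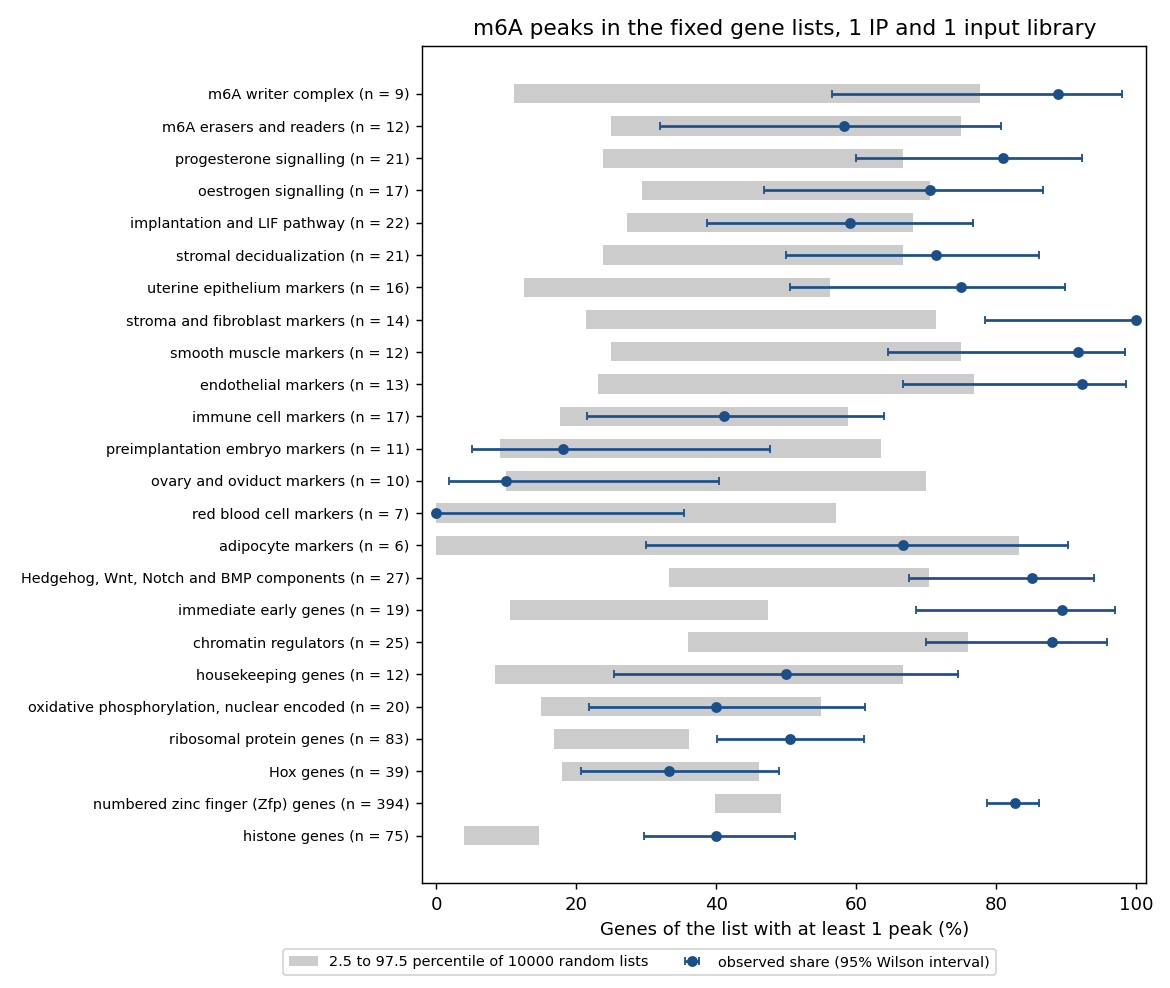
Percent of the members of each gene list with at least 1 peak (points, with 95% Wilson intervals) beside the central 95% (grey) of 10000 random lists of the same size matched on gene span. Stroma and fibroblast markers reached 100%, and red blood cell markers 0%.

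Oestrogen signalling genes had peaks in 12 of 17 cases (70.6%, 46.9 to 86.7), a count at percentile 96.9, inside the central 95% of random lists. The oestrogen receptor gene Esr1 had 16 peaks, the strongest with a fold enrichment of 13.2 (10.02 to 17.1) at chromosome 10, 4935311 to 4936068. A broad peak near the high-coordinate end of its span, at 5001037 to 5003018, had 6.42 (5.19 to 7.85) from 93 fragments. The coactivator gene Ncoa6 stood at 22.8 (17.8 to 28.7) and Cited2 at 18.9 (14.9 to 23.7). The oestrogen-induced genes Ltf and Muc1 had no peak, and neither had the other receptor genes Esr2 and Gper1. The list's percentile rose to 98.6 when only peaks with −log10 q of at least 5 were counted, and to 99.3 against random lists not matched on span. It fell to 93.1 with shared peaks counted for each gene.

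**Figure D3:**
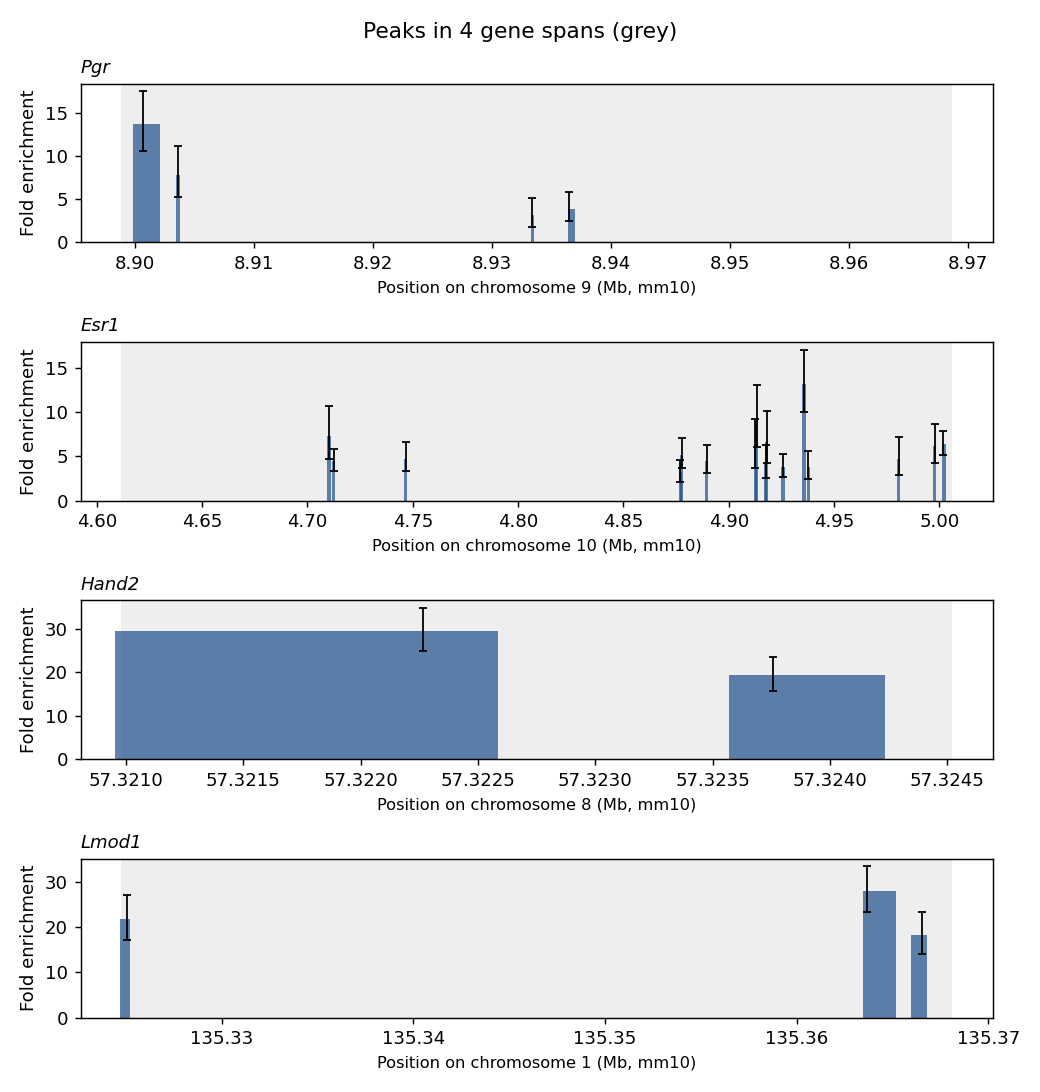
Peaks in the spans (grey) of Pgr, Esr1, Hand2 and Lmod1 on mm10, with position in Mb and fold enrichment as bar height. Bars cover each peak from start to end, error bars at the summits are exact Poisson 95% intervals of counting error, and the strongest peaks stand at 13.8, 13.2, 29.5 and 28.0.

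Genes of implantation and the leukaemia inhibitory factor (LIF) pathway did not stand out by their number of peaks, 13 of 22 (59.1%, 38.7 to 76.7; percentile 88.7). The LIF receptor genes Lifr, at 12.8 (10.1 to 16.1), and Il6st, at 13.1 (11 to 15.5), had peaks, whereas Lif itself and Stat3, the transcription factor downstream of it, had none. Wnt5a, a ligand that directs crypt formation, stood at 17.3 (13.4 to 22.1), its receptor genes Ror1 and Ror2 at 13.2 (9.06 to 18.7) and 13.0 (9.34 to 17.7), and the gland regulator Foxa2 at 15.2 (9.88 to 22.5). Msx1, a homeobox gene of the receptive uterus, had 8.36 (5.06 to 13.1). Hbegf, Ptgs2, Pla2g4a, Lpar3 and Cnr1 had no peak, and those of Msx2 and Dlx6 lay in shared spans. The list's median fold enrichment of 12.5 was at percentile 95.7.

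Stromal decidualization genes had peaks in 15 of 21 cases (71.4%, 50.04 to 86.2; percentile 99.2), with a median fold enrichment of 9.58, close to the random median of 9.55. The gene Smad1, an effector of bone morphogenetic proteins, had 28.8 (23.8 to 34.6) and the related Smad5 21.1 (16.7 to 26.3), beside 13.5 (9.10 to 19.3) in the ligand gene Bmp2. Cebpb, a transcription factor of the decidualizing stroma, had 28.3 (21.7 to 36.3), the gap junction gene Gja1 14.7 (12.2 to 17.5) and Wnt4 8.67 (4.57 to 15.3). The decidual prolactin genes Prl8a2 and Prl3c1, the cytokine gene Il11, its receptor gene Il11ra1, Wnt6 and Ccnd3 had no peak.

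Markers of all 4 main structural cell types of the uterus were among the transcripts with peaks. All 14 stroma and fibroblast markers had one (percentile 99.995), from 16.7 (13.8 to 20.1) in Col6a3 and 14.4 (12 to 17.1) in Pdgfrb to 4.03 (2.82 to 5.58) in the collagen gene Col3a1. Of the smooth muscle markers, 11 of 12 had a peak (percentile 99.9), with 28.0 (23.3 to 33.4) in the actin filament gene Lmod1, 13.8 (11.3 to 16.7) in Myh11 and lower values in the abundant transcripts Des, 5.45 (4.55 to 6.49), and Acta2, 4.63 (3.60 to 5.88). Endothelial markers had peaks in 12 of 13 cases (percentile 99.95), led by Robo4 at 21.0 (15.4 to 27.9) and the vascular cadherin gene Cdh5 at 17.6 (14.4 to 21.5). Of the epithelial markers, 12 of 16 had a peak (percentile 99.98). The transcription factor gene Elf3 stood at 14.7 (10.7 to 19.8). The gland protease genes Prss28 and Prss29 had 4.599 (3.53 to 5.90) and 4.63 (3.69 to 5.74) over backgrounds of 12.3 and 16.7, among the highest backgrounds of the list.

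Counts for markers of other cells lay inside the central 95% of random lists or, for ovary and oviduct, at its edge. Immune cell markers had peaks in 7 of 17 cases (percentile 67.1), including the complement genes C1qa, at 8.96 (6.71 to 11.7), and C1qb, at 9.84 (5.57 to 16.3), while the common leukocyte gene Ptprc had none. Preimplantation embryo markers had peaks in 2 of 11 cases (percentile 8.27), in Tfap2c and Eomes, with none in Pou5f1, Nanog or Cdx2. Ovary and oviduct markers had 1 of 10, in Ovgp1 (10%, the lower edge of the central 95%; percentile 1.51 with ties placed midway, or 2.705 with −log10 q of at least 5), and red blood cell markers 0 of 7 (percentile 7.37). Adipocyte markers had 4 of 6 (percentile 86.7), with 18.5 (11.7 to 27.8) in Fabp4 and 14.5 (8.64 to 23.0) in Adipoq, both at backgrounds of 0.192 or less. The depth over a gene without a peak is not in the data used here.

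Genes listed as m6A writers, which deposit the mark, carried peaks more often than random genes of like span. The count for the genes that remove or read it lay inside the central 95%. The lists were not tested against each other, and the intervals of their shares overlap. Of the writers, 8 of 9 had a peak (88.9%, 56.5 to 98.0; percentile 99.4), with a median fold enrichment of 14.8 at percentile 97.6. Rbm15b stood at 31.1 (25.5 to 37.7), Zc3h13, with 13 peaks, at 23.5 (19.3 to 28.5), Rbm15 at 19.7 (16 to 24.0) and Wtap at 14.9 (9.65 to 22.0). Mettl14 had 6.41 (3.17 to 11.9), and Mettl3, the catalytic subunit, had no peak. Of the erasers and readers, 7 of 12 had a peak (58.3%, 32.0 to 80.7; percentile 69.2), with a median fold enrichment of 10.3 at percentile 56.0. Both demethylase genes were among them, Fto with 10.3 (7.46 to 13.9) and Alkbh5 with 7.56 (4.95 to 11.1), as were the reader genes Ythdc1 at 23.9 (16.8 to 33.0) and Ythdf2 at 16.7 (13.3 to 20.6). The Igf2bp reader genes had none. The enrichment of the writers came to lie inside the central 95%, at percentile 97.1 with the median over each gene's peaks and 94.8 with only genes whose top peak had a pileup of at least 10.

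Developmental signalling genes and chromatin regulators carried peaks more often than random genes of like span, with high enrichment at their strongest sites. Of 27 Hedgehog, Wnt, Notch and BMP components, 23 had a peak (85.2%, 67.5 to 94.1; percentile 99.98). Their median fold enrichment was 14.1 (percentile 99.9), with 21.3 (16 to 27.7) in the Wnt coreceptor gene Lrp6, 18.9 (15.1 to 23.2) in the Wnt feedback gene Axin2 and 14.6 (9.38 to 21.8) in the Hedgehog receptor gene Ptch1. Of 25 chromatin regulators, 22 had a peak (88.0%, 70.0 to 95.8; percentile 99.95), with a median of 14.3 (percentile 99.6). The remodeller gene Chd4 reached 24.5 (19.5 to 30.4) and the methyltransferase genes Kmt2a and Kmt2d 21.5 (17 to 26.7) and 20.4 (16.7 to 24.8), whereas Ezh2, Hdac1 and Hdac2 had no peak. For both lists the enrichment held for the strongest site only. With the median over a gene's peaks it fell to percentile 88.1 for the signalling genes and 9.94 for the chromatin regulators.

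Immediate early genes, which respond to stimuli within minutes, had peaks in 17 of 19 cases (89.5%, 68.6 to 97.1), at percentile 100 of the random lists. Jun stood at 19.6 (16.3 to 23.3), Klf2 at 19.3 (15.8 to 23.5) and Myc at 14.2 (11.8 to 17), and Fos at 3.81 (1.66 to 8.03) from 5 fragments. Numbered zinc finger genes, many of them DNA-binding repressors, had peaks in 326 of 394 cases (82.7%, 78.7 to 86.2) against 44.4% in random lists (percentile 100), with a median fold enrichment of 10.6 at percentile 98.8. The Hox genes, which pattern the body axis, had peaks assigned in 13 of 39 cases (percentile 61.8). Their spans often overlap each other, and with shared peaks counted for each gene 22 of 39 had a peak (56.4%), at percentile 99.5. Hoxb8 had 24.1 (19 to 30.1) and Hoxd11 18.4 (14.1 to 23.7).

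Ribosomal protein genes with a peak had low enrichment. Of 83 ribosomal protein genes, 42 had a peak (50.6%, 40.1 to 61.1), above the 26.5% of random lists matched on span, but the median fold enrichment was 5.75 against 9.04 in random lists matched on background, below every one of them (percentile 0). The median background at their peaks was 5.40. The share itself was at percentile 96.3 against lists not matched on span, and reads of these genes can be shared with their many pseudogenes. Nuclear genes of oxidative phosphorylation had peaks in 8 of 20 cases (percentile 67.0), with a median of 6.54 at percentile 1.89, and 2.85 (1.90 to 4.13) in Cox6a1. Under 3 other settings that percentile lay between 2.58 and 5.49, inside the central 95%. Of 12 housekeeping genes, 6 had a peak (percentile 82.4), with 7.73 (6.51 to 9.12) in Actb and none in Gapdh.

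Histone genes had peaks in 30 of 75 cases (40.0%, 29.7 to 51.3) against 9.33% in random lists matched on their short spans (percentile 100). Against random lists of any span the count was at percentile 44.4. Their median fold enrichment was 9.43, close to the random median of 9.20, and near-identical copies of these genes can share reads. Among nuclear and imprinted long non-coding RNAs, 4 of 8 had a peak assigned. Malat1 had 5 peaks, the strongest with 9.57 (8.50 to 10.7) from 289 fragments, Neat1 had 11.4 (9.43 to 13.7), Meg3 8.10 (4.97 to 12.6) and Rian 5.15 (3.20 to 7.90). Peaks of 13.3 (11.6 to 15.2) in Xist and 10.7 (8.01 to 14.1) in Kcnq1ot1 lay where their spans overlap other genes, and H19 had no peak.

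Of the 24 fixed lists with a percentile for the share of genes with a peak, 13 lay above and 1, the ovary and oviduct markers tied with the edge, below the central 95% of random lists, where 1.2 would by chance. For the median fold enrichment, 5 of 20 lay above and 2 below, where 1 would by chance. With the median over each gene's peaks, 4 of the 5 came inside the central 95%, and the zinc finger genes alone lay above under both measures. Immediate early genes and the implantation list lay above under that measure alone, at percentiles 99.2 and 98.4. Ribosomal protein genes alone lay below under both.

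Along the gene, summits gathered at the ends of the span. Of 17983 summits in spans of at least 10 kb, 43.8% lay in the outer 10% at either end, against 19.98% (range 19.2 to 20.9) in 1000 random placements, and 29.97% lay in the outer 5%. Of 7070 genes, 3982 (56.3%) had summits in the outer 10% of 1 end alone, 896 (12.7%) at both ends and 2192 (31%) at neither. In Lmod1, for example, a peak of 21.7 (17.2 to 26.9) stood at the low-coordinate end and peaks of 28.0 and 18.1 near the high-coordinate end. Which end is the start of transcription could not be read from the gene table. The random placements covered introns, which fill the middle of most long spans and are removed from polyA RNA. An excess at the ends can arise from that alone.

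**Figure D4:**
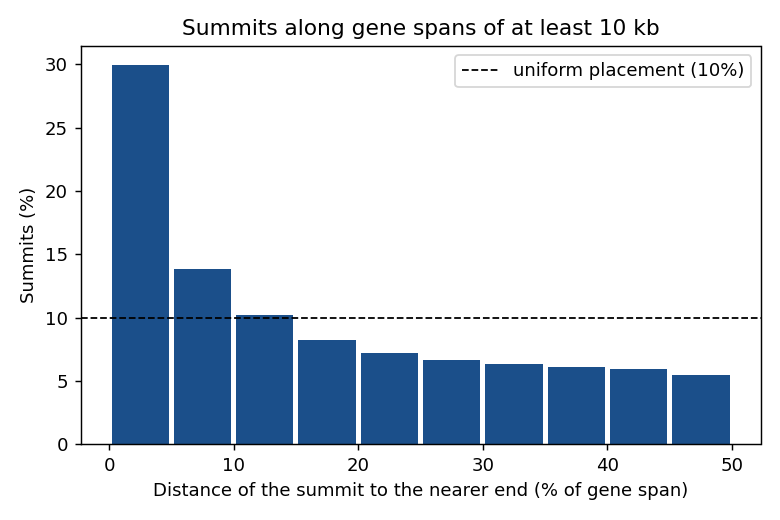
Percent of 17983 summits by distance to the nearer end of the gene span, in bins of 5% of the span, for spans of at least 10 kb. The outermost bin held 29.97% and the innermost 5.47%, against 10% in each under uniform placement over the whole span, introns included (dashed line).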

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

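The tests on the Y chromosome were chosen after their result was seen, and the lists of further liver and visceral endoderm mRNAs after the liver peaks were seen but before their own. The lists for the run name were written before any gene was looked up.

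The run name D8NegIP-Posinput on all 26584 peaks was weighed against the day 4 label. A tissue that does not express uterine identity genes was argued against. Of 16 such genes, among them Hoxd11, Emx2 and the gonadal and uterine regulator Foxl2 at 32.7 (26.1 to 40.5), 15 had a peak, at percentile 100 of random lists. The random lists hold genes of every kind, so the count cannot tell the uterus from another tissue that expresses these genes. Several of these genes are also in the progesterone and Hox lists. Day 8 implantation sites could be neither shown nor excluded, since 0 of 17 genes of day 8 decidua and gastrulating embryo had a peak (percentile 0.135), while the day 4 receptive list, with 8 of 13, stopped at percentile 93.9, short of the bound set for it, and its median fold enrichment of 5.25 was at percentile 0.830. Another uterine sample without embryos, of another day, or a name left over from another run stays open and was not tested.

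Peaks in data outside the main comparisons included 55 on the Y chromosome. Male cells were argued against as their main source, as 0 of 9 single copy Y genes had a peak against 5 of 8 of their X homologues. A share of male cells too small to give peaks in these genes stays open. Of the 55 summits, 40 (72.7%) lay in the distal 1 Mb of the annotated Y or in clusters of at least 3 within 10 kb, which is consistent with sequence shared between the Y and other chromosomes. Only 6 lay in a gene span, and the highest fold enrichment was 45.8, at 90819131 to 90820198. No other explanation was tested.

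Of 10 mRNAs typical of liver, looked up as a control tissue, 6 had peaks (60%, 31.3 to 83.2), a signal in data outside the main comparisons. Their count was at percentile 87.2, inside the central 95% of random lists of genes of every kind. The share lay above those of T lymphocyte (25%), neuron (7.14%), heart muscle (18.2%) and blood progenitor (40%) genes. Apoa1 had 25.2 (17.3 to 35.6), Ttr 10.7, Fgb 10.2 and the albumin gene Alb 5 peaks up to 8.67, and the median background at the strongest peaks of the 6 was 0.211. Liver RNA carried into the libraries in an amount that gives most liver mRNAs a peak was argued against. Of 30 further liver mRNAs, 6 had a peak (20%, 9.51 to 37.3, against a random median of 40%, percentile 0.750). Visceral endoderm of later embryos in such an amount was argued against likewise, with 1 of 12 (8.33%, 1.49 to 35.4, against 41.7%, percentile 0.930). Its member Afp, though, had been seen without a peak. Both met the bound set beforehand, the median of the random lists. Those lists hold genes of every kind, so mRNAs that the uterus does not express can meet it even if a smaller amount is present. Such an amount, for example a trace of liver RNA that shows only its most abundant mRNAs, was not tested and stays open. No other biological explanation was tested.

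The mitochondrial genome, outside the comparisons by gene, held 12 peaks covering 9671 bp, with a median fold enrichment of 3.53 and the highest, 8.19 (7.08 to 9.43), in the ribosomal RNA gene mt-Rnr2. A further 2210 summits (8.31%, 7.99 to 8.65) lay outside every gene span, with a median fold enrichment of 6.34 against 7.31 in protein-coding spans. Of the 30 peaks with the highest fold enrichment, 12 were among these, led by 75.6 (61.1 to 92.5) at chromosome 13, 9834247 to 9834630, and 74.7 (63.5 to 87.3) at chromosome 3, 5860201 to 5860779. Whether such sites are repeats, copies of ribosomal RNA or unannotated transcripts was not tested.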

How the results depend on the processing

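The alternatives that use spans of protein-coding genes only, count shared peaks within the lists, leave out genes in 2 lists, set a minimum pileup of 10 or take the outer 5% were chosen after the data were seen. With −log10 q of at least 5, summits outside every span made up 6.85%, summits in 1 protein-coding span 81.2%, and the zinc finger genes with a peak 78.2%; the cause was not tested. Counting shared peaks for each gene gave 88.1% of the zinc finger genes, 100% of the smooth muscle markers and 56.4% of the Hox genes, by its own construction, since it adds peaks. With the pseudocount in the Poisson test too, 10.2% of pileups came out whole. The other 112 values of this kind stayed within their intervals or, for counts, within 1.5 times. No list percentile went to the opposite side in 180 comparisons under alternatives, and 17 crossed a bound of the central 95%. For 21 of 25 named genes the median over the gene's peaks lay outside the interval of its strongest peak. No paired analysis was possible because there is 1 IP and 1 input sample and no test between groups. For the same reason no replicate could be left out. Merging overlapping peaks changed nothing, as none overlapped. Alternatives on exons, transcript regions, exon lengths and the DRACH motif were not run. Depth limits the 5561 peaks with pileups under 10, whose intervals are wide.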

Other observations

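The gene families here were chosen after the results for the fixed lists were seen, and the outer 5% likewise. The tests of span ends and of summits outside spans were written before their results. Enrichments of these families are those of the strongest site per gene, and the median over each gene's peaks was not run for them.

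Semaphorins and plexins, guidance ligands and their receptors, had peaks in 26 of 29 cases (89.7%, 73.6 to 96.4; percentile 100), with a median fold enrichment of 12.4 at percentile 99.2. Basic helix-loop-helix, Sox, Fox and Klf transcription factor genes had 45 of 94 (47.9%; percentile 99.2) and a median of 11.6 at percentile 98.5. Ubiquitin-specific protease genes had 36 of 50 (percentile 99.8), and PHD finger genes 13 of 21 (percentile 89.4) with a median of 13.2 at percentile 97.8.

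Mitochondrial ribosomal protein genes had peaks in 51 of 78 cases (percentile 100) but a median of 7.86 at percentile 0.920. At the strongest sites this was low, as for the cytosolic ribosomal protein genes. Translation initiation factor genes had 30 of 56 (percentile 96.5), proteasome subunit genes 13 of 40 (percentile 20.5), collagen genes 25 of 44 (percentile 44.6) and protocadherin genes outside the clusters 8 of 12 (percentile 83.3). Solute carrier genes had 142 of 346 (percentile 0.685), chemokine genes 6 of 37 (percentile 3.31) and olfactory receptor genes 7 of 1110 (0.631%; percentile 0). Among lists of tissues not sampled, T lymphocyte genes had 4 of 16 (percentile 5.32) and heart muscle genes 2 of 11 (percentile 5.32). Neuron genes had 1 of 14 (percentile 0.035) and blood progenitor genes 4 of 10 (percentile 33.8). These lists are not among the 15 added ones, which include further liver and visceral endoderm mRNAs. Of those 15, 5 lay above and 4 below the central 95% of random lists, where 0.75 would by chance.

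Summits outside gene spans may lie in part on transcript ends that extend beyond the annotated span. Of 2161 such summits on the autosomes and the X, 590 (27.3%, 25.5 to 29.2) lay within 5 kb of a protein-coding span, against 9.83% of 10000 random positions outside spans, a ratio of 2.78. The ratio leaves open enhancers, antisense transcripts and unannotated genes, which also lie near genes.

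Summits near the ends of gene spans were tested against chance placement. The 43.8% in the outer 10% lay above every one of 1000 random placements, of which the highest reached 20.9%. This argues only against uniform placement over the whole span, introns included. The marks may follow terminal exons, but introns, which fill the middle of most long spans and are removed from polyA RNA, would give the same picture, and exons were not used here.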
